A study of Mus musculus with 9 samples.

How the data were processed

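Total RNA of dendritic cells (DCs) sorted from mouse spleen was measured on 9 single-channel arrays, 1 per sample. Per the labels' protocols, the cells were gated on CD11c and MHC class II, the sort purity was stated as above a set level, and the RNA was amplified and biotin-labelled with a whole-transcript kit. Samples were grouped by the genotype in the labels into 6 controls with intact C/EBPβ and 3 knockouts without C/EBPβ, in which a Cre recombinase driven by the CD11c promoter acts on a loxP-flanked Cebpb gene. The labels name both C57BL/6 mice and Cre-only mice as sources and do not say which controls came from which. Nothing in the labels says that the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

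The deposited values are log2 intensities per probe (a transcript cluster that pools many short oligonucleotides), made by the authors with RMA per the submitters' processing notes, that is background correction, quantile normalization and a summary of the oligonucleotides. The version and settings of RMA and the genome build behind the probes are not given in the sources used here. The log base was read from the values, whose array medians lay between 5.49 and 5.56. Quantile normalization by the authors gives all arrays nearly the same distribution, so a shift of most genes in 1 direction would be removed before deposit, and RMA compresses changes of dim probes. Of 41801 rows, 7329 had no value in any sample and 4 lacked a value in 1 sample, which left 34468 probes. Probe names came from the platform's annotation table supplied with the data, where 23521 of these probes had 1 gene symbol, 1814 had several and 9133 had none. No symbol needed updating through the gene ID, and 21994 of the genes tested were found in the RefSeq gene table (GRCm38.p6), which was used only for names and for the order of neighbouring genes, so no coordinates are given.

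From these values, probes with exactly 1 symbol were kept without a filter on signal, and a gene with several probes (1082 genes) was represented by the probe with the highest mean over all samples. This gave 22180 genes. Knockout and control were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all 22180 genes with a threshold of 0.05. Changes are log2 differences of group means, knockout minus control, with limma's standard error (SE). Cebpb was also tested by an exact two-sided permutation test over the 84 ways of splitting 9 samples into 6 and 3. The number of arrays limits the precision of every value.

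Before the data were examined, 39 gene lists were fixed from general knowledge of the spleen, DCs and C/EBP factors, 15 for cell types, 23 for functions and 1 for the genes around Itgax, whose promoter drives the Cre. Of 824 list entries, 746 were measured, 32 lay only on probes of several genes and 46 had no named probe. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 39 lists. For each list the members past 0.05 were counted after adjustment over all genes and after adjustment over the list alone. The grouping, the tests, the lists, the alternatives and the rule for named genes were also set before the data were examined. The rule took Cebpb first, then the 12 genes with the largest positive and the 12 with the largest negative change among those past 0.05, leaving out predicted genes, RIKEN clones, small RNAs, pseudogenes and olfactory receptors (18 genes past 0.05). It added up to 4 members with the smallest p of each list that passed, up to 2 of each other list, and the 2 most abundant members of each cell type list. Of the genes it took, 4 immunoglobulin variable genes are given by their values and not by symbol. Genes named outside this rule are marked as chosen after their values were seen.

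Alternatives were centring each array on its median, a second quantile normalization, eBayes with trend and robust fitting, array weights (statmod 1.5.0), the replicate number as a block, controls 1 to 3 or 4 to 6 alone, each sample left out in turn, a filter on signal, the mean of a gene's probes, all probes counted as probes, a minimum change of 1.5-fold, and for lists an estimated correlation, the self-contained test fry and lists without shared genes. A B cell covariate and a count without immunoglobulin genes were added after seeing the data. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

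The scripts were tested on simulated data before use, with 22180 genes in 6 and 3 arrays, of which 200 were changed by 0.50 to 2 and 80 more, the members of 4 lists, by 0.30. The fit recovered 74.6% (50 of 67) of genes changed by 0.50 on the log2 scale, 67 of 67 changed by 1 and 66 of 66 changed by 2, and its 204 calls also held 16 of the 80 list members and 5 unchanged genes. All 4 simulated lists moved by 0.30 were called, and 0 of 16 lists left in place. Each simulated gene was drawn independently of the others, so this does not test list calls where members move together. In the measured lists the estimated correlation was 0.63 for cell cycle genes and 0.84 for red pulp macrophage markers.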

Results

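Transcript levels were measured in CD11c-positive, MHC class II-positive DCs from the spleens of naive mice, with 6 control samples and 3 samples of DCs lacking C/EBPβ. C/EBPβ is a basic leucine zipper transcription factor that acts in myeloid differentiation and inflammatory gene expression, and the design text names its part in the maturation and fate of DCs in the resting animal as the question. The array medians ranged from 5.49 to 5.56 on the log2 scale, and the correlation of any 2 arrays across probes ranged from 0.987 to 0.996. Of the 34468 probes, 1201 to 1761 had equal values in a given pair of arrays.

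Cebpb, the deleted gene, was lower in each knockout sample than in every control. Its log2 intensity in the controls was 6.77, 6.86, 7.15, 6.64, 6.66 and 6.76 in replicates 1 to 6, and in the knockouts it was 5.37, 5.60 and 5.42 in replicates 1 to 3. The mean fell from 6.81 ± 0.19 (SD, n = 6) to 5.46 ± 0.12 (SD, n = 3), a log2 change of -1.35 (SE 0.11, 95% confidence interval -1.58 to -1.11) or 2.54-fold, with limma's adjusted p = 0.00074. The exact permutation p was 0.012, the smallest that 84 splits can give. Cebpb has a single coding exon and was read by 1 probe (17379938), and the labels do not state which part of the gene was removed. The knockout level lay below the median gene at 5.92, and how much of it is background was not measured, so the fold is a lower bound on the loss if it is.

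Loss of C/EBPβ was accompanied by a rise of chemokine genes and a fall of the matrix metalloproteinase gene Mmp9. Lists of monocyte markers and phagocytic receptors were also higher and the cell cycle list lower, but these 3 passed with a preset inter-gene correlation and not with an estimated one. By the self-contained test fry their adjusted p was 0.035, 0.035 and 0.024. Among 22180 genes, 201 differed between knockout and control, of which 92 were higher and 109 lower in the knockout. The smallest change among them was 1.22-fold, and 14 genes differed by at least 2-fold. In each of the 201 genes the 3 knockout values lay outside the range of the 6 controls, as they did in 7.39% of all genes tested against the 2.38% that chance gives. The number of genes past the threshold was 33 without knockout replicate 2, 332 without knockout replicate 1, and 66, 73, 49, 64 and 60 without control replicates 1, 3, 4, 5 and 6. It was 3 against controls 1 to 3 alone, 20 against controls 4 to 6 alone, and 182 (134 higher and 48 lower) without knockout replicate 3, which carried the strongest B cell signal. The balance of directions rested on single samples too, with 78 higher and 254 lower without knockout replicate 1, 26 and 7 without knockout replicate 2, and more higher than lower without any 1 of the controls.

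The gene with the smallest p was Mid1, a microtubule-associated ubiquitin ligase whose gene spans the boundary of the pseudoautosomal region in laboratory mice. It rose from 8.33 ± 0.16 (SD, n = 6) to 10.7 ± 0.088 (SD, n = 3), a log2 change of 2.37 (SE 0.09) with limma's adjusted p = 1.6e-06. A second, dimmer Mid1 probe differed by 1.13. The labels do not show whether knockouts and controls carry the same strain DNA at this boundary, so the change cannot be assigned to loss of C/EBPβ rather than to strain. Ms4a4a, a tetraspan membrane protein, rose by 1.20 (SE 0.15, adjusted p = 0.0071), Ace, the angiotensin-converting enzyme, by 1.16 (SE 0.15, adjusted p = 0.0096), the chemokine Ccl9 by 1.13 (SE 0.09, adjusted p = 0.00083) and the interferon-inducible DNA sensor Ifi204 by 0.97 (SE 0.16, adjusted p = 0.026). The other 7 genes among the 12 with the largest increase encode immunoglobulin chains or the J chain. In their place, further genes with large increases were chosen after their values were seen. They included the lysosomal protease Lgmn (0.86), the complement C3a receptor C3ar1 (0.79), the urokinase receptor Plaur (0.92), the endosomal RNA sensor Tlr8 (0.92), the lectin Mgl2 (0.90), the metallothionein Mt1 (0.96), the transcription factor Ets2 (0.96), the metalloproteinase Mmp25 (0.80), the adhesion receptor Adgre4 (0.83), Klrb1b (0.83) and Wfdc17 (0.77).

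The largest decrease was that of Mmp9, which encodes gelatinase B. Its intensity fell from 8.71 ± 0.17 (SD, n = 6) to 6.35 ± 0.16 (SD, n = 3), a log2 change of -2.35 (SE 0.11) or 5.11-fold, with limma's adjusted p = 2.9e-06. Cebpb itself came next, followed by the succinate receptor Sucnr1 (-1.11, SE 0.14, adjusted p = 0.0071) and Serpinb2 (-0.89, SE 0.17, adjusted p = 0.045), an inhibitor of plasminogen activators. Slc14a1, a urea transporter, fell by 0.74. The remaining 7 genes of the 12 were Timeless (-0.80), Cdca7 (-0.77), Tcf19 (-0.74), Cdca7l (-0.71), Asf1b (-0.68), Cdca5 (-0.66) and the histone gene H2bc12 (-0.84), most of which act in replication, chromatin assembly or chromosome segregation.

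Of the 57 named genes past 0.05, 19 stayed past it whichever sample was left out: Cebpb, Mid1, Mmp9, Sucnr1, Ms4a4a, Ace, Ccl9, Ccl6, Ccl17, Osm, Lgmn, Klrb1b, Mmp25, C3ar1, Wfdc17, Fcgr2b, Prdm1, Ube2c and 1 kappa variable gene. The other 38 missed 0.05 in at least 1 of these smaller fits. The numbers lost were 26, 14, 22, 30, 27 and 27 without control replicates 1 to 6 in turn, and 11, 37 and 19 without knockout replicates 1 to 3 in turn. The counts of list members given with each gene group moved with them, and in the 7 lists that passed with 2 members past 0.05 this count ranged from 0 to 3 over the same fits.

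**Figure D1:**
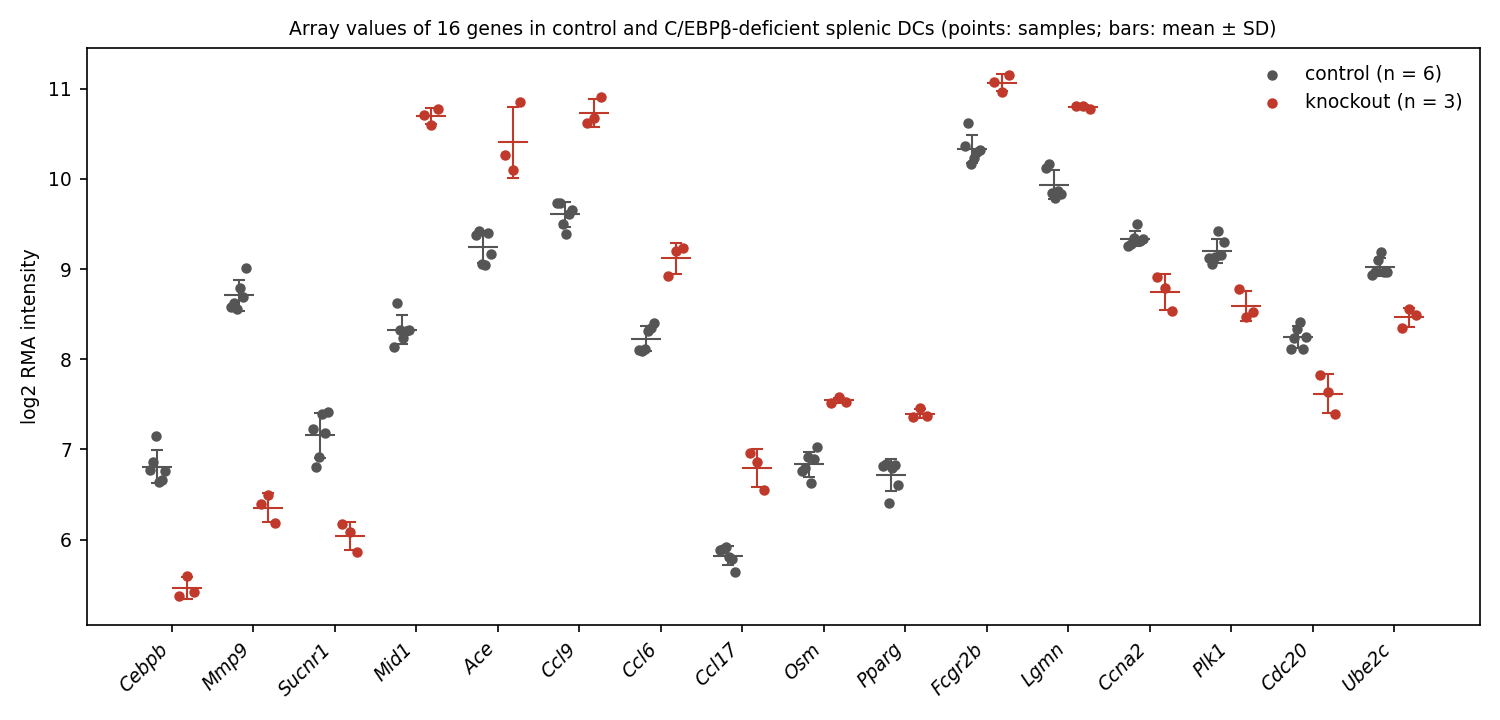
Log2 RMA intensity (vertical axis) of 16 genes (horizontal axis) in 6 control and 3 knockout samples; points are samples and bars are means ± SD. Cebpb, Mmp9 and Sucnr1 and the cell cycle genes Ccna2, Plk1, Cdc20 and Ube2c lie lower in the knockout, and in each plotted gene the knockout points lie outside the control range.

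Immunoglobulin genes rose without a matching rise of the median of other B cell markers in 2 of the 3 knockout samples. Of 21 immunoglobulin genes tested, 7 were higher and 0 lower by limma. The largest change was that of the kappa variable gene Igkv6-23 (3.86, SE 0.53, adjusted p = 0.011). Igkv6-14 rose by 2.15, 3 other kappa variable genes by 3.12 (SE 0.31, adjusted p = 0.0024), 2.18 and 1.40, a heavy chain variable gene by 1.59, and Jchain, the J chain of secreted IgA and IgM, by 1.89 (adjusted p = 0.046). The median of the 17 variable genes relative to the control mean was 0.88, 1.63 and 1.73 in knockout replicates 1 to 3, against -0.52 to 0.76 in the controls. The same median over 14 B cell markers other than immunoglobulins was 0.018, -0.078 and 0.53, against -0.052 to 0.086 in the controls, and Cd79a reached 10.2 in knockout replicate 3 against 7.29 to 8.24 in the controls. In knockout replicate 1, Cd79a (8.67), Blk (8.08) and Ebf1 (6.36) also lay above every control, while Cd22 (9.90) lay below every control and Fcmr (7.48) within their range. The number of immunoglobulin genes past the threshold was 10 without knockout replicate 1, 1 without knockout replicate 2, 4 without knockout replicate 3, and 4, 3, 3 and 4 without control replicates 2, 4, 5 and 6. For Ighm, whose brightest probe differed by 0.17 (adjusted p = 0.68), the 7 probes ranged from 0.17 to 2.48.

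Of the 39 gene lists, 18 passed 0.05 with the preset correlation, 16 higher and 2 lower in the knockout, and 2 of them held with an estimated correlation. These 2 were the cytokine and chemokine genes and the myeloid genes reported to depend on C/EBP factors. In 9 of the 84 splits of the samples, the real one included, as many lists passed with the preset correlation.

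Chemokine and cytokine genes rose together. In this list 7 of 33 measured members rose and 0 fell, or 16 and 0 adjusted over the list alone, with a median change of 0.29 (limma's camera adjusted p = 2.5e-17, and adjusted p = 0.015 with an estimated correlation). Beside Ccl9, the related chemokine Ccl6 rose by 0.89 (SE 0.10, adjusted p = 0.0044), Ccl17, a ligand of the receptor CCR4, by 0.97 (SE 0.09, adjusted p = 0.0024), and Osm, a cytokine of the interleukin-6 family, by 0.71 (SE 0.08, adjusted p = 0.0053). The count of 7 became 4 without control replicate 1 or without knockout replicate 2. The list of reported C/EBP-dependent myeloid genes was also higher, not lower, in the knockout, with a median of 0.19 (adjusted p = 2.2e-08, and adjusted p = 0.015 with an estimated correlation). In it 2 of 27 members rose and 0 fell, or 8 and 0 adjusted over the list alone, namely Pparg (0.68, SE 0.10, adjusted p = 0.016), a nuclear receptor for lipids, and the fatty acid-binding protein Fabp4 (0.47, SE 0.09, adjusted p = 0.046). Retnla (0.69, adjusted p = 0.086) and Csf3r (0.46, adjusted p = 0.057) did not pass. Without knockout replicate 2 the number of members that passed was 0, and without knockout replicate 1 or any control it was 1. The 8 became 4 without knockout replicate 2 and 5 without control replicate 4 or 6. In a comparison chosen after the values were seen, this list's mean went with that of the red pulp macrophage markers over the 6 controls (Pearson r = 0.91), as did that of the cytokine and chemokine list (r = 0.71). Control replicate 2, with those markers 0.66 above the control mean, had 0.094 for this list and 0.089 for the cytokine list. Knockout replicates 1 to 3, with the markers at 0.20, 0.70 and 0.65, had 0.24, 0.25 and 0.22 for this list. For the cytokine list they had 0.34, 0.40 and 0.30. This argues against a larger share of red pulp macrophages as the whole cause of either rise. It does not address monocytes or other macrophages. The mean of the monocyte and macrophage list was 0.23, 0.36 and 0.45 in knockout replicates 1 to 3. In control replicate 2, the highest control, it was 0.17. A larger share of these cells stays open for both lists. How much of each rise lies outside monocytes and macrophages was not determined. Within the C/EBP family list, which did not pass (6 members, adjusted p = 0.94), Ddit3 rose by 0.42 and Cebpb fell.

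Genes of DC maturation rose in part, and over the 6 controls this list's mean went with that of the red pulp macrophage markers (r = 0.82). Control replicate 2, with those markers 0.66 above the control mean, had 0.054 for this list. Knockout replicates 1 and 2, with the markers at 0.20 and 0.70, had 0.21 and 0.32. In these 2 samples that argues against a larger share of red pulp macrophages as the whole cause. A larger share of monocytes or other macrophages stays open. Knockout replicate 3 (markers 0.65, list 0.11) lay nearer the highest control (0.066), and the rise is not placed within DCs. In this list 2 of 26 members rose and 0 fell, or 6 and 0 adjusted over the list alone, with a median of 0.20 (adjusted p = 1.5e-07, and adjusted p = 0.16 with an estimated correlation). The 2 were Ccl17 and the second CCR4 ligand Ccl22 (0.45, SE 0.07, adjusted p = 0.025), while the lymph node homing receptor Ccr7 (0.41, adjusted p = 0.16) and the costimulatory ligand Tnfsf9 (0.63, adjusted p = 0.12) did not pass. The 6 became 3 without control replicate 3 and 2 without control replicate 4 or 6 or knockout replicate 1 or 2. The NF-kB targets had a median of 0.22 with 0 of 23 members past 0.05 over all genes and 3 higher adjusted over the list alone (adjusted p = 2.7e-08, and adjusted p = 0.15 with an estimated correlation). The 3 became 0 without control replicate 3, 4 or 6 or knockout replicate 1 or 2, 1 without control replicate 5, 5 without control replicate 1 and 7 without knockout replicate 3, when 1 also passed over all genes. Among these targets, Ccl4 differed by 0.48 and Tnfaip3 by 0.37. The immediate early genes had a median of 0.16, with 0 of 25 past 0.05 and 7 higher adjusted over the list alone (adjusted p = 7.7e-08, and adjusted p = 0.26 with an estimated correlation), and among them Atf3 differed by 0.56 (adjusted p = 0.053). The 7 became 0 without knockout replicate 1 or 2, 2 without control replicate 3, 4, 5 or 6 and 3 without control replicate 1, and over all genes 2 passed without control replicate 2 and 1 without knockout replicate 3. The groups overlapped in the mean of this list, which relative to the control mean was 0.24 in control replicate 2, -0.20 in control replicate 1 and 0.18, 0.28 and 0.16 in knockout replicates 1 to 3. The STAT3 targets Il4ra (0.43) and Socs3 (0.39) rose, 2 of 19 in a list with 5 higher and 1 lower adjusted over the list alone and a median of 0.16 (adjusted p = 9.0e-05, and adjusted p = 0.16 with an estimated correlation). Without knockout replicate 2 that median was 0.096, and the 5 became 3, or 2 without knockout replicate 1. Among inhibitory and tolerance genes, 2 of 27 rose, the inhibitory receptor Lilrb4a (0.63, adjusted p = 0.034) and Socs3, or 3 adjusted over the list alone, with a median of 0.077 (adjusted p = 5.4e-05, and adjusted p = 0.13 with an estimated correlation). The 3 became 7 without knockout replicate 3.

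Phagocytic and pattern recognition receptors were higher as a list with the preset but not with the estimated correlation, as were the 2 lists of macrophage markers. In this list 4 of 32 members rose and 0 fell, or 11 and 1 adjusted over the list alone, with a median of 0.21 (adjusted p = 1.3e-07, and adjusted p = 0.15 with an estimated correlation). The 4 were the inhibitory Fc receptor Fcgr2b (0.74, SE 0.09, adjusted p = 0.0086), Tlr8, the beta-glucan receptor Clec7a (0.52, SE 0.09, adjusted p = 0.031) and the lectin Cd209a (0.54, SE 0.10, adjusted p = 0.046), of which a second Cd209a probe differed by -0.63. The count of 4 was 1 without control replicate 1, 3 or 4 or without knockout replicate 1 or 2, and 2 without control replicate 5 or 6. The mean of this list relative to the control mean was 0.26, 0.31 and 0.30 in knockout replicates 1 to 3, 0.17 in control replicate 2 and -0.18 in control replicate 3. That of the red pulp macrophage markers was 0.20, 0.70 and 0.65 in the knockouts and 0.66 and -0.59 in the same controls. Over the 6 controls the 2 lists went together (r = 0.95 without the 1 shared gene), and the values do not place the rise within DCs. Lipid genes had a median of 0.086 (adjusted p = 0.0076, and adjusted p = 0.16 with an estimated correlation), with the desaturase Scd1 (0.87) and Fabp4 past 0.05 among 29, and 8 higher and 4 lower adjusted over the list alone, or 4 and 2 without knockout replicate 1 or 2. The 4 lower also became 2 without control replicate 3 or 5 or knockout replicate 3. The median of the lipid genes was 0.14 without control replicate 5 or knockout replicate 1 or 3. Migration and adhesion genes had a median of 0.058 (adjusted p = 0.016, and adjusted p = 0.16 with an estimated correlation), with 0 of 20 past 0.05, or 1 higher adjusted over the list alone, and Cxcr4 at 0.57 (adjusted p = 0.051). The migration list missed the threshold without control replicate 3 (adjusted p = 0.062) and without knockout replicate 1 (adjusted p = 0.093). Its median was 0.035 without control replicate 3 and 0.038 without knockout replicate 2, and without knockout replicate 3, 2 members passed over all genes.

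The heat shock genes were higher as a list in the knockout, with 12 of 12 members above 0 and a median of 0.36 (adjusted p = 9.6e-09, and adjusted p = 0.15 with an estimated correlation). Over all genes 0 of the 12 passed, and 6 were higher adjusted over the list alone. Without knockout replicate 3, 3 passed over all genes. The list's mean relative to the control mean was 0.84, 0.43 and 0.13 in knockout replicates 1 to 3, against -0.095 to 0.12 in the controls. Knockout replicate 3 thus lay barely above the highest control. The largest difference was that of the co-chaperone Bag3 (1.40, SE 0.33, adjusted p = 0.082), with 10.4, 9.14 and 8.31 in knockout replicates 1 to 3 against 7.89 ± 0.11 (SD, n = 6) in the controls. The chaperone genes Dnajb1 and Hspa1b differed by 0.58 and 0.34 and did not pass.

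Cell cycle genes fell, and 33 of 33 measured members lay below 0. The median was -0.56 (adjusted p = 1.7e-26, and adjusted p = 0.15 with an estimated correlation), and 7 members fell over all genes, or 30 adjusted over the list alone. Cyclin A2 (Ccna2) fell by 0.59 (SE 0.09, adjusted p = 0.017), the polo-like kinase Plk1 by 0.61 (SE 0.10, adjusted p = 0.024), Cdc20, an activator of the anaphase-promoting complex, by 0.62 (SE 0.10, adjusted p = 0.026) and the ubiquitin-conjugating enzyme Ube2c by 0.56 (SE 0.07, adjusted p = 0.011). The list's median relative to the control mean was -0.27, -0.49 and -0.95 in knockout replicates 1 to 3, against -0.14 to 0.16 in the controls. The 7 became 24 without knockout replicate 1, 1 without knockout replicate 2, 3 without knockout replicate 3, control replicate 3 or control replicate 4, 2 without control replicate 6 and 4 without control replicate 1 or 5. Oxidative phosphorylation was the other list that fell, by a median of 0.13 with 32 of 35 members below 0 (adjusted p = 7.2e-07, and adjusted p = 0.24 with an estimated correlation). None of its members passed over all genes (0 of 35 by limma), 1 was lower adjusted over the list alone, and the median was -0.071 without knockout replicate 3. The respiratory subunit gene Ndufa4 differed by -0.33 (adjusted p = 0.068).

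**Figure D2:**
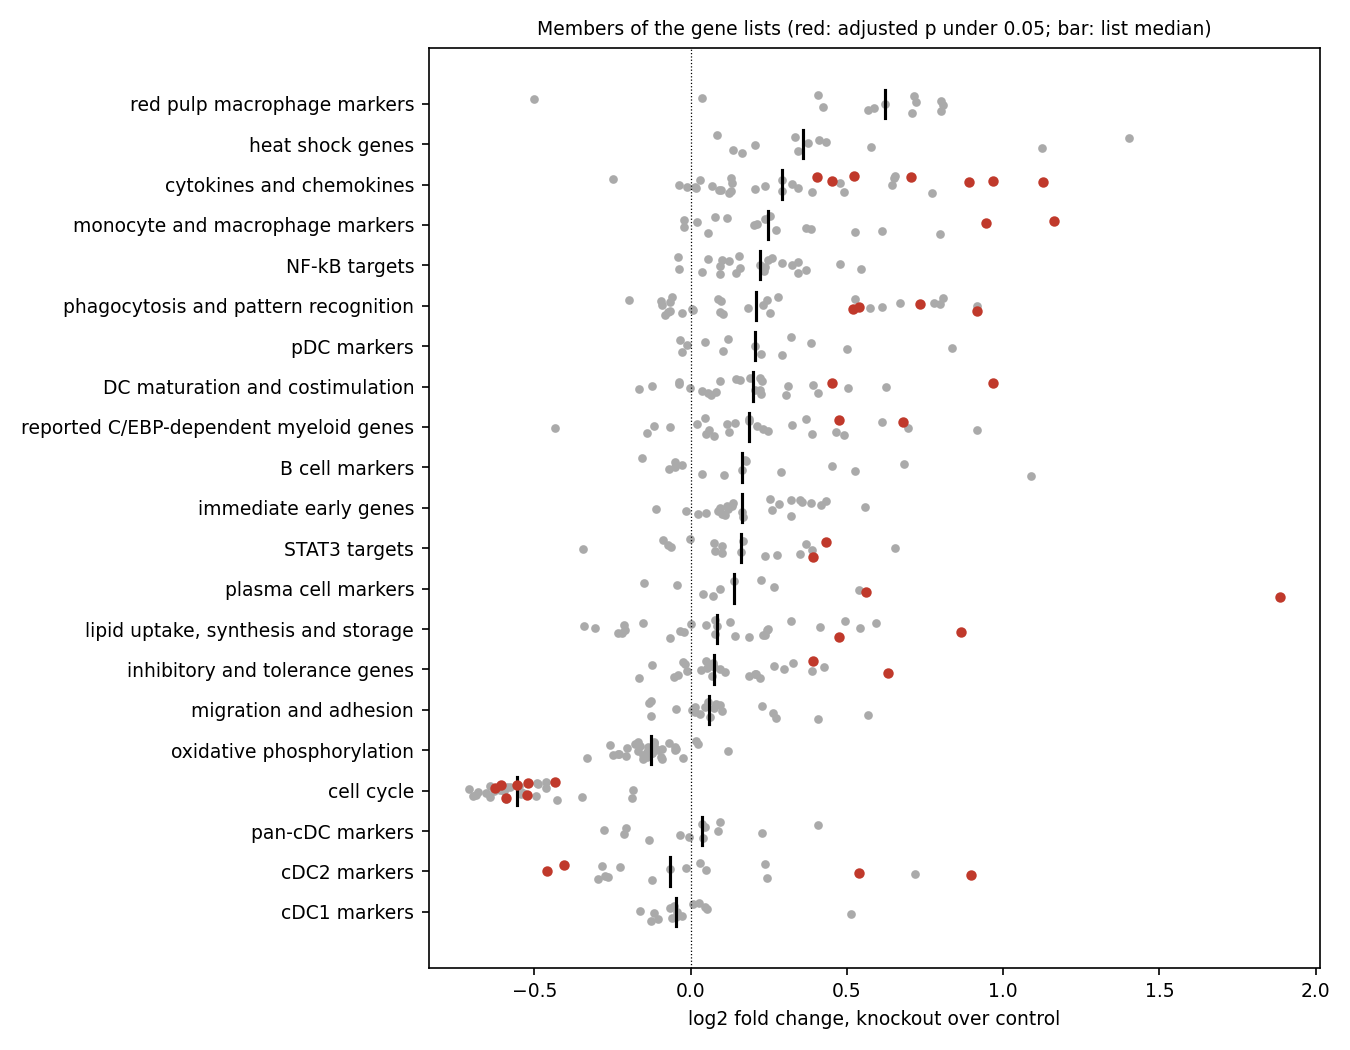
Log2 fold change, knockout over control (horizontal axis), of the measured members of 21 gene lists (vertical axis). Each point is a gene, red where limma's adjusted p was under 0.05, and the black bar is the list's median, which was -0.56 for cell cycle genes and 0.62 for red pulp macrophage markers.

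Markers of conventional DCs as a whole did not pass. Those of monocytes, red pulp macrophages, plasma cells, B cells and plasmacytoid DCs passed with the preset correlation and none of them with an estimated one, and those of T and NK cells passed with neither. The pan-cDC markers had a median of 0.036, or -0.0058 after a second quantile normalization, with 0 of 13 past 0.05 over all genes (adjusted p = 0.71) and 1 higher and 2 lower adjusted over the list alone. The MHC class II genes H2-Ab1, the member at the median, and H2-Aa differed by 0.036 and 0.094. The cDC1 markers had a median of -0.047 with 0 of 15 past 0.05 (adjusted p = 0.68) and 0 adjusted over the list alone, with the integrin Itgae at 0.51 and Naaa at -0.16. In the cDC2 list, with a median of -0.066 (adjusted p = 0.57), 2 of 17 members rose (Cd209a and Mgl2) and 2 fell, among them Dtx1 (-0.46, SE 0.07, adjusted p = 0.018), a regulator of Notch signalling. Adjusted over the list alone, 3 rose and 5 fell. Over all genes, the 2 that rose became 0 without any of control replicates 1 to 5 or without knockout replicate 1 or 2. The 2 that fell became 1 without any control or knockout replicate 3 and 0 without knockout replicate 2. The abundant cDC2 genes Cd7 and Cd4 differed by -0.23 and -0.26 and did not pass.

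Monocyte and macrophage markers rose with a median of 0.25 (adjusted p = 4.0e-08, and adjusted p = 0.13 with an estimated correlation). In this list 2 of 18 members rose and 0 fell, or 5 and 0 adjusted over the list alone, namely Ace and Ms4a7 (0.95, SE 0.17, adjusted p = 0.034), while the Fc receptor Fcgr1 (0.80, adjusted p = 0.070) and the receptor Csf1r (0.37, adjusted p = 0.097) did not pass and Cd68 differed by -0.020. The 5 became 3 without knockout replicate 2. The median of this list was 0.15, 0.24 and 0.29 in knockout replicates 1 to 3 and -0.17 to 0.15 in the controls, and control replicate 2 lay above knockout replicate 1. Red pulp macrophage markers had the highest median of any list, 0.62 (adjusted p = 1.9e-07, and adjusted p = 0.26 with an estimated correlation). None of the 13 passed over all genes (0 by limma) and 8 were higher adjusted over the list alone, a number that was 0 without knockout replicate 2 and 0 without knockout replicate 3. The list's median was 0.31, 0.78 and 0.73 in knockout replicates 1 to 3 and -0.56 to 0.62 in the controls, so the groups overlapped. Axl differed by 0.81 (adjusted p = 0.081), Vcam1 by 0.80, Spic by 0.71 and Cd163 by 0.42.

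Plasma cell markers rose with a median of 0.14 (adjusted p = 0.00040, and adjusted p = 0.13 with an estimated correlation), with 2 of 11 past 0.05 over all genes and 2 adjusted over the list alone, Jchain and Prdm1 (0.56, SE 0.07, adjusted p = 0.0059), a transcription factor that DCs also use. Without control replicate 1 the median was 0.22, and the count over the list alone was 4 there and without knockout replicate 2. The abundant plasma cell gene Xbp1 differed by 0.041. B cell markers had a median of 0.17 (adjusted p = 0.018, and adjusted p = 0.60 with an estimated correlation) with 0 of 15 past 0.05 and 0 adjusted over the list alone. That list's adjusted p was 0.66, with a median of -0.011, without knockout replicate 3, and 0.055 without control replicate 6, while without knockout replicate 2 the median was 0.28, with 1 member past 0.05 over all genes and 4 over the list alone. Plasmacytoid DC markers had a median of 0.21 (adjusted p = 0.0026, and adjusted p = 0.26 with an estimated correlation) with 0 of 13 past 0.05 and 0 adjusted over the list alone. Over the 6 controls this list's mean went with that of the red pulp macrophage markers (r = 0.89). Without knockout replicate 3 that list did not pass (0.065, adjusted p = 0.13), and its mean was higher in control replicate 2 (0.23) than in knockout replicates 1 and 2 (0.044 and 0.19). Klk1 differed by 0.84 and Siglech by 0.29.

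The remaining lists did not pass. With those of conventional DCs and the C/EBP family they made 21, and 19 of the 457 values of these 21 over the alternatives passed. Among cell types the remaining lists were markers of neutrophils (16 measured members with a median of 0.037, adjusted p = 0.47), T cells (12 with 0.013, adjusted p = 0.64), NK cells (12 with 0.046, adjusted p = 0.19), erythroid cells (8 with 0.099, adjusted p = 0.14), platelets and megakaryocytes (9 with 0.067, adjusted p = 0.16), mast cells and basophils (10 with 0.047, adjusted p = 0.21) and stromal and endothelial cells (13 with -0.027, adjusted p = 0.94). Mmp9 was the 1 member of these lists past 0.05. Adjusted over the list alone, 1 neutrophil marker rose and 1 fell, 2 erythroid markers rose and 1 fell, 1 platelet marker rose, and 0 of the other 4 lists changed. Among functions the lists were MHC class II presentation (16 members with a median of -0.0092, adjusted p = 0.57), MHC class I presentation (16 with -0.059, adjusted p = 0.46), type I interferon response (24 with -0.087, adjusted p = 0.65), mTORC1 signalling (30 with -0.043, adjusted p = 0.94) and glycolysis (21 with -0.10, adjusted p = 0.71). Fatty acid oxidation (25 with -0.042, adjusted p = 0.71), cholesterol synthesis (19 with -0.11, adjusted p = 0.20), the unfolded protein response (21 with 0.016, adjusted p = 0.11) and cytosolic ribosomal proteins (21 with -0.085, adjusted p = 0.080) complete these. Without knockout replicate 3 the median was -0.014 for glycolysis, 0.0081 for mTORC1 signalling, -0.016 for MHC class I presentation and -0.040 for the interferon response. Some of these lists passed when 1 sample was left out. They were the unfolded protein response without knockout replicate 3 (0.066, adjusted p = 0.00084), ribosomal proteins without knockout replicate 2 (-0.15, adjusted p = 0.0024) or control replicate 1 or 2, and cholesterol synthesis without knockout replicate 2 (-0.19, adjusted p = 0.0092) or control replicate 1. The NK cell list passed without knockout replicate 2 (0.12, adjusted p = 0.028) and the erythroid list without control replicate 4 (0.12, adjusted p = 0.032). Within them Lgmn, the interferon-inducible genes Ifi204 and Rsad2 (0.57, adjusted p = 0.048), Scd1, Pparg and Ddit3 rose. Adjusted over the list alone, 3 interferon genes rose and 3 fell, 3 mTORC1 genes rose and 3 fell, 1 rose in each of the C/EBP family, MHC class II, MHC class I, glycolysis, fatty acid oxidation, cholesterol and unfolded protein lists, Cebpb fell, and 0 ribosomal genes changed. The 10 genes around Itgax, with a median of -0.012 (adjusted p = 0.71), held 0 past 0.05 and 0 adjusted over the list alone. Camera's direction opposed the sign of the median in the MHC class II, mTORC1 and Itgax lists, and that of the mean in the cDC2, neutrophil and interferon lists. After a second quantile normalization the median changed sign in the C/EBP family (0.0051) and fatty acid oxidation lists (0.0077).

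**Figure D3:**
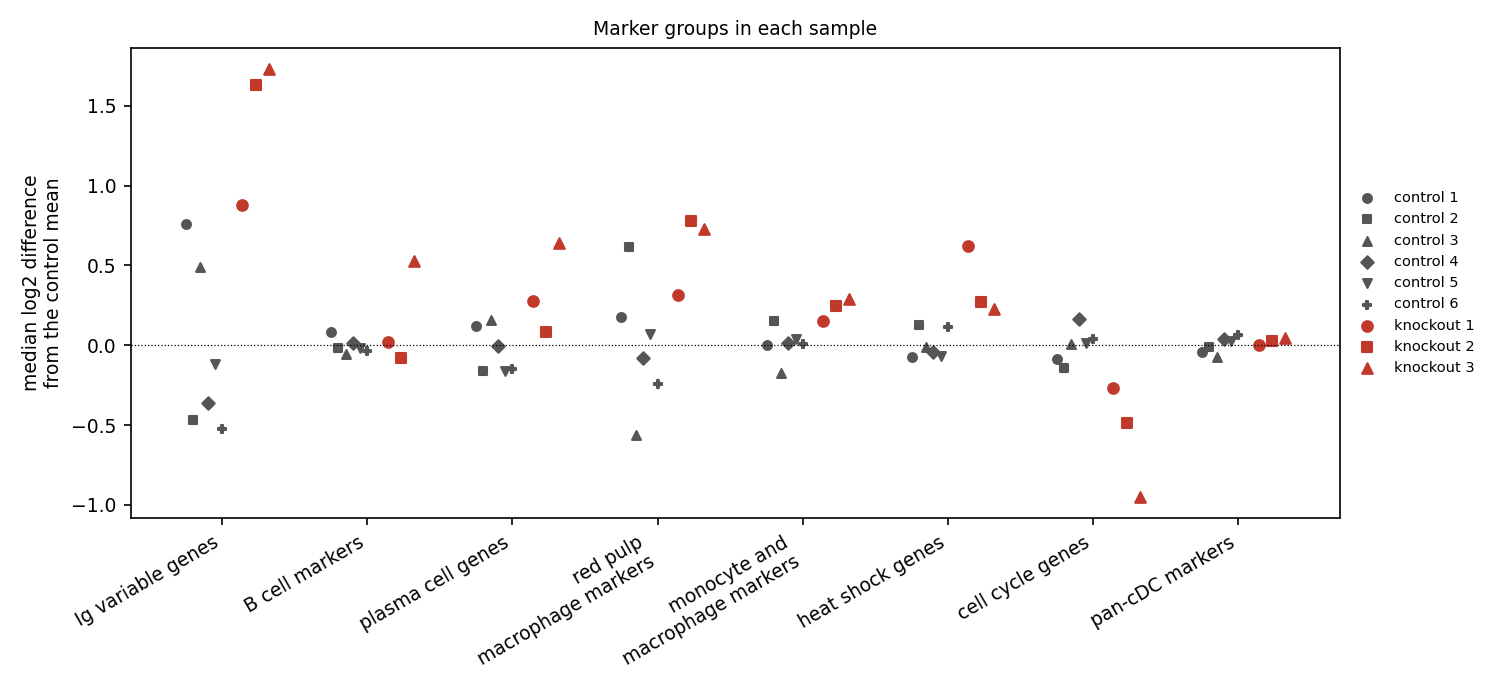
Median log2 difference from the control mean (vertical axis) of 8 gene groups (horizontal axis) in each of 9 samples, controls in grey and knockouts in red. Immunoglobulin variable genes lay at 0.88 to 1.73 in the knockouts, B cell markers reached 0.53 in knockout replicate 3 alone, and cell cycle genes lay at -0.27 to -0.95.

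The samples separated by genotype along the first principal component, which held 30.1% of the variance, with controls from -14.5 to -0.28 and knockouts at 8.0, 13.8 and 26.3. Along the second, which held 16.3%, control replicates 1 to 3 lay at 6.98 to 12.1 and control replicates 4 to 6 at -4.48 to -3.33, while knockout replicates 1, 2 and 3 lay at -15.2, -11.8 and 9.92. The labels give no batch that matches this separation of the controls. Whether it follows the mouse line of the controls cannot be told, since the labels do not say which line each control came from.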

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

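Among the tests in this part, those of B cell markers, of neutrophil genes, of pan-cDC markers and of the genes named for Esam-high cDC2 were chosen only after values of the genes concerned had been seen, as was the fit with a B cell covariate. The bounds for the neutrophil and pan-cDC tests were also revised after their values were known.

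Immunoglobulin variable genes were higher in the 3 knockout samples by medians of 0.88, 1.63 and 1.73. The test of a larger share of B cells took knockout replicates 1 and 2 together, where 14 B cell markers had a mean median of -0.030 (SE 0.040) against 1.25 for the variable genes. This argues against such a share in replicate 2, where the markers' median was -0.078. In replicate 1 it was 0.018, but Cd79a, Blk and Ebf1 lay above every control and Cd22 below, so a larger share of B cells stays open there. It also stays open for knockout replicate 3, where the markers reached 0.53 (SE 0.052), between the bounds set for either answer. A larger share of plasma cells may account for part of the signal in knockout replicate 3, where 5 plasma cell genes had a median of 0.64 (SE 0.16). For replicates 1 and 2 together the test decided neither way, since 0.18 lay within its error (SE 0.12) of the bound of 0.20. In replicate 1 the median was 0.28, above every control (highest 0.16), and in replicate 2 it was 0.085, within the control range. Jchain, counted here among the immunoglobulin genes, was 8.63 and 9.76 in replicates 1 and 2, against at most 8.06 in the controls. A larger share of plasma cells therefore stays open in both. Immunoglobulin transcripts are abundant in antibody-secreting cells, so a few such cells that passed a sort on CD11c and MHC class II could suffice. Differences between mice in antibody repertoire, or an effect of genotype on them, were not tested.

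Mmp9 fell by 2.35 on the log2 scale in the knockout, with 3 of 3 samples below every control. A loss of neutrophils, which the sort on CD11c and MHC class II is meant to remove, is argued against by levels in the controls. Neutrophils would bring their abundant transcripts along, but 11 other neutrophil genes, S100a8 (3.23), S100a9 (5.08) and Camp (4.16) among them, had a median of 4.65 (SD 1.32 across genes) against 8.71 for Mmp9. All 11 lay below Mmp9, the brightest being Csf3r at 8.02, which is not specific to neutrophils. Levels of different probes compare only roughly, and as 9 of the 11 lay below the median gene at 5.92, their median change of 0.047 adds nothing. DNA of another strain carried along with the engineered Cebpb locus stays open, because Mmp9 lies on the same chromosome with 34 measured genes between them. Among the 50 measured genes nearest to Cebpb, 25 on each side, 11 had an unadjusted p under 0.05, against a median of 7 and a 95th percentile of 12 in runs of neighbouring genes elsewhere (percentile 87.9), which decides neither way. These 50 stop short of Mmp9, so the genes next to Mmp9 were not examined. A dependence of Mmp9 on C/EBPβ in DCs is therefore a hypothesis beside that of linked DNA, and no test run here separates it from linked DNA. Typing strain variants between Cebpb and Mmp9 in these mice, or measuring Mmp9 in DCs of mice with the loxP-flanked gene and no Cre, would do so.

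Cell cycle genes were lower in the knockout, with a median of -0.56. A smaller share of conventional DCs as the whole cause is argued against, since it needs their markers to fall about as far. Of the 13 pan-cDC markers, 4 lay within 2 log2 units of the top of the arrays' range, and the other 9 had a median of -0.034 (SD 0.23 across markers, SE of the difference 0.083) and a lowest change of -0.28. As 5 of the 9 lay below 0 and 4 above, a smaller fall of that share stays open. A smaller share of Esam-high cDC2, a dividing DC subset of the spleen, stays open as a candidate for part of the fall, since Esam (-0.27), Dtx1 (-0.46), Clec4a4 (-0.30), Cd4 (-0.26) and Cd7 (-0.23) had a median of -0.27 (SE 0.055), although only Dtx1 of the 5 passed 0.05. The rule here asked only that these genes fall, not that they fall as far as the cell cycle genes. The median of the 5 genes, -0.27, was a smaller fall than -0.56. The rule for conventional DCs was not run on these 5 genes. It would leave out Cd7, which lay within 2 log2 units of the top of the arrays' range. Whether a smaller share of Esam-high cDC2 is the whole cause was therefore not decided. In the samples the median of the 5 genes was -0.093, -0.24 and -0.40 in knockout replicates 1 to 3, and the cell cycle median was -0.27, -0.49 and -0.95. A lower division rate within each subset was not tested.

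Of the 84 ways of splitting the samples into 6 and 3, the real one gave 201 genes past 0.05 and the highest of the others gave 0. The exact permutation p is then 0.012, the smallest that 84 splits can give, which argues against chance and does not exclude it. Every other split puts knockouts and controls into 1 group, which widens the spread within it and can lower the count. For the number of gene lists past 0.05 with the preset correlation the splits do not exclude chance, since 9 splits gave as many as the real 18 and the highest of the others gave 20, among them splits that put 3 controls together.

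In the 6 controls, 10 of 191 gene and list values had a sample far from the other 5, and chance gives about 1 in 20. Control replicate 1 had Ebf1 at 6.23 (others 5.73 to 5.90), Vwf at 6.49 (others 6.75 to 6.77) and the mean of the B cell markers at 7.75 (others 7.56 to 7.63). Control replicate 4 had Cox6a2 at 5.75 (others 6.08 to 6.27), Ccna2 at 9.50 (others 9.25 to 9.34) and the mean of the erythroid markers at 6.04 (others 5.84 to 5.90). Control replicate 6 had Il2rb at 5.52 (others 5.83 to 5.92) and Nlrc5 at 9.02 (others 9.34 to 9.43). Itgb3 was 7.84 in control replicate 2 (others 7.97 to 8.03) and Cdh5 was 7.27 in control replicate 5 (others 6.84 to 6.97).

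Probes outside the gene comparison also differed. Of 10947 probes with no gene symbol or several, 68 passed 0.05, 57 higher and 11 lower in the knockout, and 15 of the 68 had several symbols. The largest difference was that of the unnamed probe 17549018, at 4.59 in the controls and 10.1 in the knockouts (5.54, SE 0.22, limma's adjusted p = 1.1e-06), followed by the unnamed probes 17284662 (4.67) and 17284657 (4.57). These 2 are numbered on either side of an Ighm probe (17284660, 2.48). Others that rose, such as 17459338 (2.85) and 17467516 (2.53), are numbered close to kappa variable probes. None of these is shown to be separate from the immunoglobulin signal. A probe shared by Ighm and a heavy chain variable gene rose by 1.56. The smallest p was that of the unnamed probes 17549014, 17549136 and 17549148, which had the same group means (4.07, limma's adjusted p = 2.8e-07) and count as 3 of the 68. Probe numbers are not coordinates, and what the unnamed probes measure was not determined. A probe shared by Mid1 and another gene differed by 1.15, and probes shared by the Dynlt1 family by -0.49 to -0.65.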

How the results depend on the processing

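The fits with a B cell covariate and without immunoglobulin genes were chosen after seeing the data, and the other alternatives were planned. The number of genes past 0.05 was 201 (45.8% higher). It was 152 with centred arrays, 267 with quantile normalization, 247 with trend and robust, 186 with probe means, 183 over all probes (63.9% higher) and 183 without immunoglobulin genes. It was 652 with array weights, 20 with controls 4 to 6 and 3 with controls 1 to 3, 532 over the brighter genes, 83 with a 1.5-fold minimum (61.4% higher) and 123 with the B cell covariate (71.5% higher, 79 shared with the 201). Leaving out each sample gave 33 to 332 genes, and 93 of the 182 without knockout replicate 3 were among the 201. Fewer samples or fewer tested genes are the construction of several of these, and otherwise the cause was not tested. Array signal over background was not given, so its limit on dim genes was not measured.

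The Cebpb change stayed past 0.05 in all alternatives but the block, at -1.41 to -1.28 with each sample left out. The number of lists past 0.05 was 18, 17 to 21 with a sample left out, 13 by fry and 2 with an estimated correlation, which widens the null when members move together. The 13 by fry were 12 of the 18 and the platelet list (fry adjusted p = 0.035). The 6 that missed by fry were red pulp macrophages (0.16), plasmacytoid DCs (0.16), B cells (0.51), immediate early (0.16), lipid (0.059) and migration genes (0.071). Of the 57 named genes past 0.05, Mid1 and Mmp9 passed under all 19 alternatives run on them. Of 1079 alternative values of the 57 genes, 398 missed 0.05 and 1 changed sign. Of 1797 values of the other 95 named genes, 80 passed 0.05 and 23 changed sign. The replicate numbers do not pair the samples, since same-numbered samples had correlations of deviations of -0.14, -0.10 and 0.047. With the replicate number as a block, 2 genes passed and Cebpb was at -1.47 (adjusted p = 0.14), and knockout replicate 3 correlated best with control replicate 2, not its own number.

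Signs changed for Cd209a (0.54) and the B cell list's median (0.17), which had passed 0.05, and for genes that had not, of which Bst2 (0.22) and Ighm (0.17) had the largest changes. Of 457 values of the 21 lists that did not pass, 52 had the opposite direction, 8 each for the cDC1 and glycolysis lists. Where no cause is named, the cause was not tested. With quantile normalization H2-Ab1 was -0.0058 and Kdr 0.037. With array weights Ighm was -0.0059 and Car2 0.0069. With the block, and with controls 1 to 3 alone, Bst2 was -0.0092 and Kdr 0.039. With controls 4 to 6 alone Cd68 was 0.0056. With the mean of its 2 opposed probes Cd209a was -0.046. With the B cell covariate Ighm was -0.064, Cd8b1 0.018, Car2 0.040 and the B cell list's median -0.013. With a sample left out, log2 changes ranged from -0.085 to 0.042 for Cd68, -0.080 to 0.33 for Ighm, -0.0099 to 0.13 for Xbp1, -0.16 to 0.049 for Cd8b1, -0.18 to 0.068 for Car2, -0.18 to 0.31 for Itgb3, -0.19 to 0.011 for Kit, -0.17 to 0.016 for Pecam1, -0.067 to 0.039 for Kdr and -0.011 to 0.28 for the B cell list's median.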

Other observations

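The groups in this part were assembled after the values of all genes had been seen, so they describe these samples and test nothing. Beyond the genes of the cell cycle list, further genes of the replication fork fell in the knockout. Among them were the polymerase subunits Pole (-0.64, SE 0.12, limma's adjusted p = 0.039) and Pole2 (-0.59, SE 0.08, adjusted p = 0.0095). Others were the replicative helicase component Cdc45 (-0.51), the checkpoint mediator Clspn (-0.65) and the helicase Blm (-0.49). The single histone genes H1f2 (-0.48, SE 0.06, adjusted p = 0.0071), H2ac10 (-0.47), H4c12 (-0.33) and H2ax (-0.56) also fell, and histone genes as a group were not tested.

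Several receptors outside the lists rose in the knockout. They were the interleukin-7 receptor Il7r (0.71, SE 0.09, limma's adjusted p = 0.0086), the death receptor Fas (0.63, SE 0.07, adjusted p = 0.0042), Cd93 (0.63), Slamf9 (0.56), the sphingosine phosphate receptor S1pr3 (0.63) and Csf2rb2 (0.50). The transcription factors Maf (0.66), Vdr (0.76) and Nfe2l2 (0.49), the last a regulator of the antioxidant response, rose with Xdh (0.66), Sqor (0.57) and Got1 (0.67). Of the neighbours of Cebpb, 2 passed 0.05 with opposite signs, Sulf2 (0.43) and a RIKEN clone gene, 5031425F14Rik (-0.65).

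Mid1 differed in all 3 knockout samples without a difference of sex between the samples. Xist, transcribed from the inactive X chromosome, was at 11.3 ± 0.18 (SD, n = 6) in the controls and 11.2 ± 0.058 (SD, n = 3) in the knockouts, and the Y-linked genes Kdm5d and Uty were at 3.17 and 3.70 in the controls and 3.16 and 3.72 in the knockouts, far below the median gene at 5.92. A difference of strain DNA at Mid1 was not tested.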
